A study of Mus musculus with 6 samples.

How the data were processed

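Agilent arrays of mouse RNA with 2 colours were read from the scanner files of 6 hybridisations, 4 of shLoxl2 and 2 of shSnail RNA, each with shGFP RNA in the other channel. The direction of each ratio was taken from the dyes in the labels. Per the labels, RNA was amplified and labelled with a linear amplification kit. Spot intensity values in both channels were deposited as extracted by Agilent Feature Extraction, version 9.5.1.1 per the file headers and version 6.1.1 per the submitters' processing notes. Per the file headers the arrays were read on an Agilent scanner, whereas a label names another maker's. The deposited log10 ratios of Cy5 over Cy3 were also made by that software, per the file headers. The authors' value table holds those log10 ratios rounded. Each column except that of shSnail replicate 2 matched its own array within 0.006 at 100% of spots, with Cy5 over Cy3 as its direction and no further centring. Its medians ran from 0.0371 to 0.098 by array. Both shSnail columns of that table matched the scanner file of shSnail replicate 1, while the scanner file of replicate 2 matched its own column at 9.37% of spots and correlated with that of replicate 1 at 0.79. The table was therefore used only as an alternative, with 1 shSnail array.

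From the mean intensities and local background medians, each array was corrected by normexp with an offset of 50 and normalized by loess in limma 3.58.1, with the 736 control spots and outlier spots at weight 0. The 21318 probe spots were averaged to 20868 probes, and 19718 probes well above background in at least 1 channel on at least 2 arrays were tested. Names came from RefSeq accessions (assembly GRCm38.p6) for 14767 probes and from the files for 6101. Probe coordinates are those of the files, in mm8. Several probes of a gene were represented by the brightest tested, which gave 18557 names. Among the named genes, other probes of Tnc, Ski, Ereg, Nsdhl, Nefl, Cxadr, Dsp, Itgav and Spred1 differed from the one used in direction or in passing the threshold.

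The 2 arrays of each shLoxl2 number were read as a technical dye swap of 1 RNA sample and averaged with the sign turned, which cancels the dye effect. Against shGFP, shLoxl2 was fitted with the 2 shSnail values sharing the estimate of spread. For shSnail, whose arrays had 1 orientation, each probe's dye effect was estimated from the sums of dye-swapped shLoxl2 ratios and removed. shSnail against shLoxl2 used the 4 Cy5 arrays. Tests were limma's lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05, in R 4.3.3 with data.table (version 1.17.8). The fits, the 21 gene lists, the rule for named genes and most alternatives were set before the data were examined. That rule took, for each comparison, Loxl2 and Snai1, the 10 largest rises and falls past the threshold with a gene symbol and the same direction on every array, with the 5 smallest p given as not passing where fewer than 5 passed, and up to 4 members of each list by smallest p. Lists were tested by camera with a preset correlation of 0.01, with an estimated correlation and fry beside it, 1 probe per gene. With an estimated correlation, camera had only the residual degrees of freedom, 2 in shLoxl2 and in shSnail against shLoxl2 and 3 in shSnail. A list could therefore lose its call there whatever its correlation. By fry, which asks whether a list's genes move on balance 1 way, the keratinocyte, cell cycle and epithelial lists (adjusted p = 0.0188 for each), the hypoxia list (0.0359) and the interferon list (0.0395) passed in shLoxl2, and the ER stress list did not (0.158). In shSnail the 6 lists that passed camera had fry adjusted p from 0.00214 to 0.0206, and the epithelial and mesenchymal lists (0.00214 for each) and the TGF-beta and hypoxia lists (0.0157 for each) passed fry but not camera. In shSnail against shLoxl2 the keratinocyte and epithelial lists passed fry (0.00627 for each), and the EMT (0.0871), matrix (0.106), cytokine (0.106), Wnt (0.0934) and ER stress (0.0948) lists passed camera but not fry. In shLoxl2 the cytokine list had a negative median and mean but a camera direction upward, and the matrix list a negative median and a positive mean.

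In 20 simulations on 19718 probes with known changes, 97.4% of 2-fold changes were recovered for shLoxl2 against shGFP, 73.4% for shSnail against shGFP and 43.2% for shSnail against shLoxl2. False calls made up 7.15%, 7.5% and 5.73% of calls, above the nominal 5% in each. The simulated shSnail arrays carried the dye effect of the shLoxl2 arrays in full. On the real shSnail arrays its slope was 0.449 among dimmer and 0.508 among brighter probes. The figures for the 2 comparisons with shSnail therefore leave out errors from an inexact dye correction. No simulated array carried an error of the shared shGFP RNA, so the figures for both comparisons with shGFP also leave out the control's own spread. Each simulated silencing changed 200 probes, whereas 2728 and 4203 probes were called in the data for shLoxl2 and shSnail against shGFP.

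Alternatives were no background subtraction, the scanner software's log ratio, the deposited value table, scaling between arrays, other filters on dim probes, a 2-fold minimum, an adjusted p below 0.10, single dye orientations, no dye correction, a random block for the RNA sample, the replicate number as a block, and each replicate left out. The dye effect measured on the shLoxl2 arrays predicted the shSnail ratios with a slope of 0.449 among the dimmer probes, so a correction scaled by that slope was added after the data were seen. Green negative controls had medians of 676.4 to 858.6 on the shLoxl2 arrays and 292 to 354 on the shSnail arrays, against 77.99 to 87.53 in red on all 6, which limits the signal over background of dim probes in green. The design text gives another number of hybridisations than the labels, and the labels were followed.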

Results

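RNA from mouse HACA cells carrying a short hairpin against Loxl2 (shLoxl2) or against Snail (shSnail) was hybridised together with RNA from control cells carrying a hairpin against GFP (shGFP) on 6 Agilent 2-colour arrays. A short hairpin RNA lowers the transcript it is directed against. Loxl2 encodes a lysyl oxidase-like enzyme, and Snail is the zinc-finger repressor encoded by Snai1, a regulator of epithelial-mesenchymal transition (EMT). There were 4 shLoxl2 arrays, an array in each dye orientation for each of 2 replicate numbers, and 2 shSnail arrays, both with the silenced RNA in Cy5, so n = 2 in each silenced group. The labels do not say whether the 2 samples of a group came from separate cultures, so the spread between samples behind the p-values may be technical. The p-values of shSnail against shGFP also rest on how the dye effect varied between the 2 dye-swapped shLoxl2 pairs. Both tests against shGFP treat an averaged shLoxl2 pair and a single shSnail array as equally variable. The shGFP RNA was the other channel of every array and counted as 1 control sample, so the tests of a ratio against 0 leave out the control's own spread. Between 85.4% and 92.4% of probe spots were well above background in the red channel and between 55.9% and 74.9% in the green channel, and 19718 of 20868 probes were tested. The small number of arrays limits the precision.

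The silenced transcripts were examined first. The Loxl2 probe (chromosome 14, 68427414 to 68427473, mm8) had a log2 fold change of 0.11 (SE 0.12, n = 2, limma adjusted p = 0.59) in shLoxl2 cells. It was well above background on 2 of the 4 shLoxl2 arrays in the silenced channel and on 1 in the control channel. With the silenced RNA in Cy5 alone its value was -0.99, and with the silenced RNA in Cy3 alone it was 1.21, with a dye effect of -1.10 on this probe. In shSnail cells Loxl2 was at 0.27 after dye correction (limma adjusted p = 0.377) and at -0.83 without it (limma adjusted p = 0.00533). The Snai1 probe (chromosome 2, 167233778 to 167233837, mm8) was not well above background in either channel of the 2 shSnail arrays, so no fold was measured there. In shLoxl2 cells Snai1 was well above background in 0 of 4 silenced channels and 2 of 4 control channels, and it did not pass (limma adjusted p = 0.676). These probes therefore do not check the labels of the silenced groups, and the directions below rest on the labels alone.

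The dye effect, the part of a ratio that did not turn with the dyes on the shLoxl2 arrays, had an SD of 0.46 on the log2 scale over probes and a correlation of 0.79 between the 2 dye-swapped pairs. It passed the threshold for 4917 probes. It exceeded the responses among dim probes and fell below them among bright ones. Both shSnail arrays had 1 orientation, so their values depend on how this effect is removed. With the sign turned, the 2 arrays of a shLoxl2 number correlated across probes at only 0.0226 for replicate 1 and -0.0319 for replicate 2. Arrays of different replicates in 1 orientation correlated at 0.719 in Cy3 and 0.753 in Cy5. The averages of the 2 dye-swapped pairs, in which the dye effect cancels, correlated at 0.676.

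**Figure D1:**
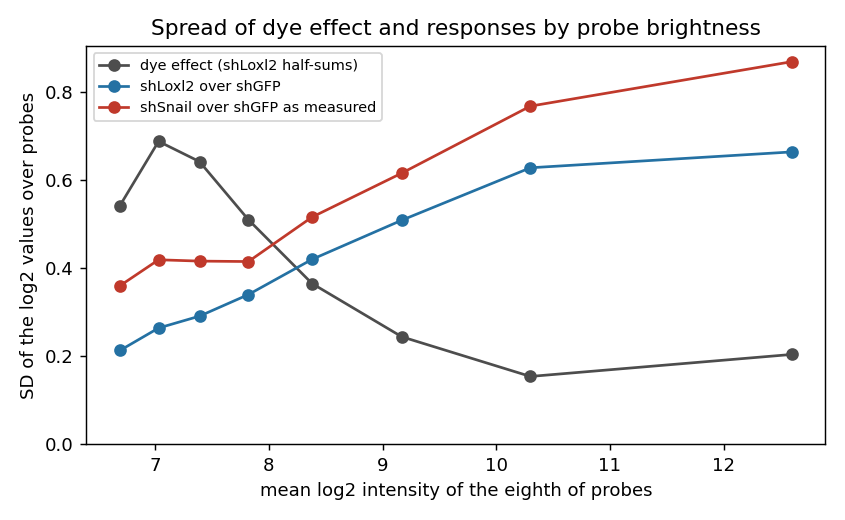
SD over probes of the dye effect (grey), of the shLoxl2 response (blue) and of the shSnail response as measured (red), on the log2 scale, against the mean log2 intensity of each eighth of the probes. The SD of the dye effect was highest at 0.69 among dim probes and lowest at 0.15 in the next to brightest group.

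The first comparison asks what changed in shLoxl2 cells relative to shGFP cells. Genes of the cornified layer of the epidermis had the largest rises. Asprv1, a skin protease (chromosome 6, 86594991 to 86595050, mm8), was 32.0-fold higher (log2 fold change 5.0, SE 0.21, n = 2, limma adjusted p = 0.000594). Kprp, a keratinocyte proline-rich protein, was 28.8-fold higher, and Klk7, a protease that acts in skin shedding, was 21.4-fold higher. The other 7 of the 10 largest rises were Crct1, the late cornified envelope genes Lce1m, Lce3c, Lce1b and Lce1a2, and the small proline-rich genes Sprr2f and Sprr2d, between 13.9-fold and 21.2-fold higher. The silenced channel was saturated for Crct1 on 3 of the 4 arrays and for Lce3c on 1, which lowers the measured folds. The largest fall was that of Csf2, the cytokine GM-CSF, at -3.69 on the log2 scale (SE 0.30, n = 2, limma adjusted p = 0.00243). Nppb, a natriuretic peptide, was at -3.51, the keratin Krt23 at -3.49, Slitrk6 at -2.87 and Fst, which encodes the activin antagonist follistatin, at -2.77. Il6, Tcim, Pde4b, Ptger2 and Dhrs1 completed the 10 largest falls, between -2.76 and -2.55.

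Of 54 keratinocyte differentiation genes tested, 24 rose and 6 fell in shLoxl2 cells, with a median log2 fold change of 0.50 (camera adjusted p = 3.38e-06). Adjusted over the list alone, 27 rose and 8 fell. The call was lost with an estimated correlation (adjusted p = 0.581). That form of the test had only 2 residual degrees of freedom, so such a loss need not come from correlation between genes. Sprr1b rose by 2.77 on the log2 scale (SE 0.11) and Cnfn, which encodes cornifelin, by 3.49 (SE 0.15). The median of the 31 members outside the Krt, Sprr, Lce, Klk, S100 and Serpinb families was 0.07, of which 9 rose and 5 fell. The epidermal transcription factor Trp63, named after its values were seen, fell by 1.15 (SE 0.12).

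Cell cycle genes fell in shLoxl2 cells. Of 57 tested, 30 fell and 2 rose, with a median of -0.72 (camera adjusted p = 1.02e-10, and adjusted p = 0.581 with an estimated correlation). Adjusted over the list alone, 34 fell and 3 rose. The mitotic cyclin Ccnb2 was at -1.96 (SE 0.11), the cytokinesis regulator Ect2 at -1.74 (SE 0.12), the spindle checkpoint gene Mad2l1 at -1.49 (SE 0.11) and the mitotic kinase Aurka at -1.53 (SE 0.11).

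Of 32 genes of ER stress and the amino acid response, 8 fell and 1 rose, with a median of -0.24 (camera adjusted p = 0.0154, and adjusted p = 0.581 with an estimated correlation). Adjusted over the list alone, 9 fell and 1 rose. Cth, an enzyme of cysteine synthesis, was at -1.67 (SE 0.15) and the stress factor Ddit3 at -0.94 (SE 0.13), while Chac1 rose by 1.17 (SE 0.13). The silenced channel of Chac1 was saturated on 2 of the 4 arrays. The other 18 of the 21 lists did not pass, with medians from -0.15 to 0.17 and camera adjusted p from 0.0561 to 0.939. Of 52 epithelial adhesion and polarity genes, 9 rose and 5 fell (camera adjusted p = 0.0586), and adjusted over the list alone 12 rose and 7 fell. Crb3, a polarity gene, rose by 2.33 (SE 0.11) and Epcam by 1.51 (SE 0.11), while the integrin Itgb4 was at -1.88 (SE 0.11), with its control channel saturated on 1 of the 4 arrays. Cdh1, which encodes E-cadherin and was named after its values were seen, rose by 1.08 (SE 0.12, limma adjusted p = 0.00494). Among 12 EMT transcription factors, Tcf3 rose by 0.66 (SE 0.12), and Snai2 and Tcf4 were at -0.97 (SE 0.18) and -0.68 (SE 0.14). The matrix protease Mmp3 rose by 2.71 (SE 0.11).

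In total 1579 probes rose and 1149 fell in shLoxl2 cells at an adjusted p below 0.05. The count was 774 with the scanner software's own log ratios and 1733 without shLoxl2 replicate 1.

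**Figure D2:**
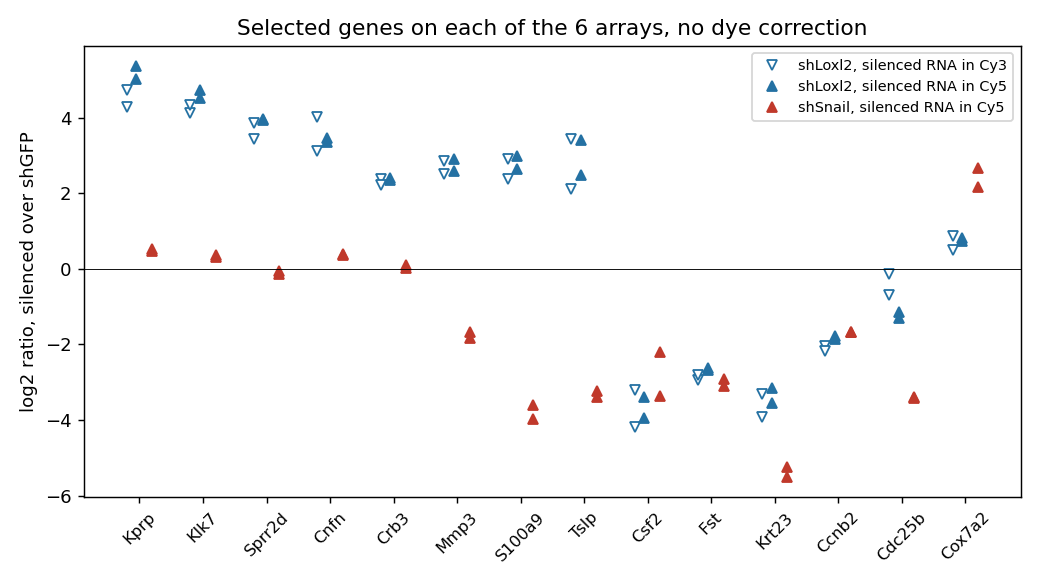
Log2 ratio of silenced over shGFP RNA for selected genes on each of the 6 arrays, with no dye correction. Open downward triangles are shLoxl2 arrays with the silenced RNA in Cy3, filled blue triangles shLoxl2 arrays with it in Cy5, and red triangles shSnail arrays. Kprp and Klk7 lay high on all 4 shLoxl2 arrays, and S100a9 and Tslp lay above 0 in shLoxl2 and below 0 in shSnail.

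The second comparison asks what changed in shSnail cells relative to shGFP cells. The keratin Krt23 (chromosome 11, 99294169 to 99294228, mm8) had the largest fall, at -5.51 on the log2 scale (SE 0.20, n = 2, limma adjusted p = 0.000418). The calcium-binding proteins S100a8 and S100a9 were at -4.55 (SE 0.34) and -3.87 (SE 0.20), the prolactin-family gene Prl8a9 at -4.49 (SE 0.14) and thrombomodulin, Thbd, at -3.83 (SE 0.17). Ifi202b, Serpinb2, the epithelial cytokines Tslp and Il33, and Nppb completed the 10 largest falls, between -3.72 and -3.19. The homeobox gene Rhox5 had the largest rise, at 4.38 (SE 0.48, n = 2, limma adjusted p = 0.00255). Ift27, the transcription factor Klf2, Crct1, the respiratory chain subunit Cox7a2, Ly6g6c, Atp5k and Rps27l rose by between 2.25 and 2.56. Without dye correction Crct1, Ly6g6c and Atp5k were at 1.83, 1.70 and 1.85, and Ift27, Klf2, Cox7a2 and Rps27l between 2.08 and 2.47. Rps6kl1 and Cgref1 were not well above background in the control channel of both shSnail arrays. Without dye correction they were at least 6.64-fold and 5.56-fold higher. Their fitted folds with dye correction were lower than these bounds, at 6.13 and 5.35. Such a bound sets the mean of the brighter channel against the lowest signal well above background, or the dim probe's own where higher, and is open to dye bias here because both arrays had 1 orientation.

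Of 57 cell cycle genes, 34 fell and 0 rose in shSnail cells, with a median of -0.76 (camera adjusted p = 2.9e-10, and adjusted p = 0.191 with an estimated correlation). Adjusted over the list alone, 36 fell. The phosphatase Cdc25b was at -3.00 (SE 0.17), Ect2 at -2.51 (SE 0.15), Ccnb2 at -1.82 (SE 0.13) and Aurka at -1.77 (SE 0.14). Of 46 matrix remodelling genes, 17 fell and 1 rose (median -0.63, camera adjusted p = 0.000212), and 20 fell and 1 rose adjusted over the list alone. The protease inhibitor Serpinb2 was at -3.51 (SE 0.24), thrombospondin Thbs2 at -1.85 (SE 0.16) and the metalloproteases Mmp14 and Mmp3 at -1.53 (SE 0.13) and -1.79 (SE 0.16). The median of this list was -0.271 with no background subtraction, -0.334 with no dye correction and -0.421 with the dye effect scaled. Its call was lost with an estimated correlation (adjusted p = 0.446).

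Of 54 keratinocyte differentiation genes, 19 fell and 4 rose in shSnail cells (median -0.30, camera adjusted p = 0.00093), and 21 fell and 6 rose adjusted over the list alone. The water channel Aqp3 was at -2.33 (SE 0.16) and Sprr2h at -2.33 (SE 0.16). Of 12 EMT transcription factors, 5 fell and 0 rose (median -0.635, camera adjusted p = 0.00224), and 9 fell and 1 rose adjusted over the list alone. Snai2 was at -1.60 (SE 0.24), Tcf4 at -1.35 (SE 0.18), Twist2 at -0.90 (SE 0.13) and Foxc2 at -0.88 (SE 0.13). Of 39 cytokine and chemokine genes, 11 fell and 1 rose (median -0.41, camera adjusted p = 0.00188), and 16 fell and 2 rose adjusted over the list alone. Il33 was at -3.25 (SE 0.16) and the signalling inhibitor Socs3 at -2.20 (SE 0.14), while Hmox1, heme oxygenase, rose by 1.66 (SE 0.15). Of 47 growth factor and MAPK genes, 15 fell and 2 rose (median -0.41, camera adjusted p = 0.00188), and 17 fell and 2 rose adjusted over the list alone. The median of this list was -0.124 with the dye effect scaled and -0.117 with no background subtraction. The MAPK inhibitor Spred1 was at -2.17 (SE 0.16) and the Kit ligand Kitl at -2.09 (SE 0.16). Another Spred1 probe was at -0.695. These 4 lists also lost their calls with an estimated correlation (adjusted p = 0.446 for each). The other 15 of the 21 lists did not pass, with medians from -0.28 to 0.28 and camera adjusted p from 0.0848 to 0.881. Among them, the cytoskeleton and migration list passed with no dye correction (17 fell and 3 rose, camera adjusted p = 0.00542) and with the dye effect scaled (16 fell and 4 rose, camera adjusted p = 0.0049). Both calls were lost with an estimated correlation (adjusted p = 0.678 and 0.635). Of 52 epithelial adhesion and polarity genes, a list that also did not pass, 11 fell and 3 rose (median -0.13, camera adjusted p = 0.22). The leukocyte, endothelial, and muscle and neural marker lists had medians of 0.04, -0.06 and 0.09.

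In total 1729 probes rose and 2474 fell in shSnail cells after a dye effect measured on the shLoxl2 arrays was removed, and 2571 rose and 3623 fell without that correction. With the dye effect scaled before removal, a treatment chosen after seeing the data, 1766 rose and 2807 fell. Across probes the shSnail log2 fold changes correlated with the dye effect at -0.425 after full removal, 0.362 without correction and 0.00351 with scaling. Between full removal and no correction 995 rises and 2004 falls were shared and 225 probes were called in opposite directions. The scanner software's log ratios, whose median over probes was -0.28, gave 1012 rises and 3172 falls. With either shSnail array left out, 1584 and 1993 probes were called.

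**Figure D3:**
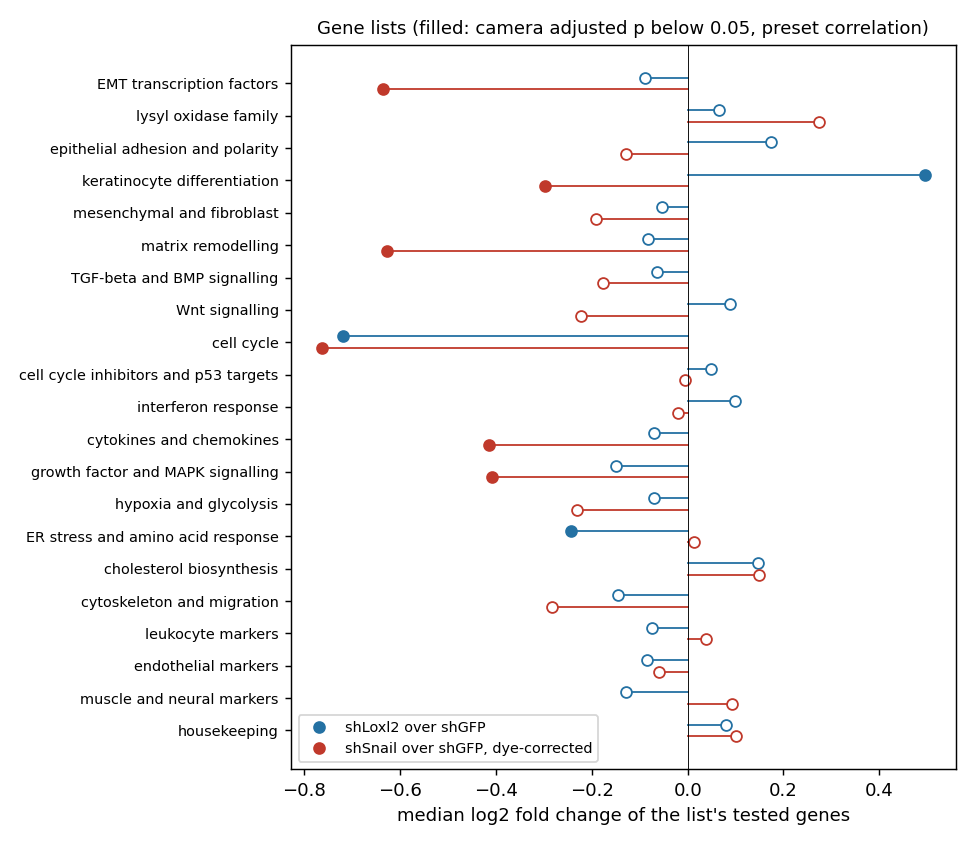
Median log2 fold change of the tested genes of each of the 21 lists in shLoxl2 (blue) and shSnail (red, dye-corrected) cells over shGFP cells. Filled points passed camera at an adjusted p below 0.05 with the preset correlation. The cell cycle medians lay at -0.72 and -0.76, and the keratinocyte differentiation medians at 0.50 and -0.30.

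The third comparison sets shSnail against shLoxl2 cells on the 4 arrays with the silenced RNA in Cy5. It takes the dye effect as equal on all 4. That effect, measured on the shLoxl2 arrays, predicted the shSnail ratios with a slope of 0.449 among dimmer and 0.508 among brighter probes. The differences may thus subtract too much dye effect, and no alternative with a scaled dye effect was run for them. Negative values are lower in shSnail. S100a9 differed the most, by -6.59 on the log2 scale (SE 0.21, limma adjusted p = 0.00235, 2 arrays against 2). Prl8a9 differed by -6.45 (SE 0.16), Tslp by -6.25 (SE 0.33), S100a8 by -5.53 (SE 0.21), Prl2c3 by -5.53 (SE 0.16) and Sprr2f by -5.50 (SE 0.23). Kprp, Mmp3, Klk7 and Asprv1 completed the 10 largest negative differences, between -4.69 and -4.21. Trappc6a had the largest positive difference, 2.43 (SE 0.27), followed by Dpm3, the respiratory chain genes Uqcr10 and Ndufa9, Adm, Ift27, Nosip, Tagln, the mitochondrial pyruvate carrier Mpc1 and Brk1, between 2.05 and 2.32.

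Of 54 keratinocyte differentiation genes, 30 were lower and 0 higher in shSnail than in shLoxl2 (median -1.05, camera adjusted p = 5.54e-12, and adjusted p = 0.473 with an estimated correlation). Adjusted over the list alone, 35 were lower and 2 higher. Krt16 differed by -4.13 (SE 0.16) and Sprr2d by -4.05 (SE 0.15). Of 52 epithelial adhesion and polarity genes, 16 were lower and 1 higher (median -0.325, camera adjusted p = 0.00481, and adjusted p = 0.542 with an estimated correlation), and 19 were lower and 2 higher adjusted over the list alone. Crb3 differed by -2.31 (SE 0.15) and Epcam by -1.32. Of 46 matrix remodelling genes, 15 were lower and 1 higher (median -0.34, camera adjusted p = 0.00481, and adjusted p = 0.644 with an estimated correlation), and 16 were lower and 2 higher adjusted over the list alone. Mmp13 differed by -3.66. Of 39 cytokine and chemokine genes, 11 were lower and 0 higher (median -0.30, camera adjusted p = 0.0134), and 14 were lower and 1 higher adjusted over the list alone, among them Ccl2 at -3.08. Of 12 EMT transcription factors, 2 were lower and 0 higher (median -0.61, camera adjusted p = 0.00832), with 5 lower adjusted over the list alone. The Wnt list had 3 lower and 0 higher of 34 (median -0.35, camera adjusted p = 0.0403), as many adjusted over the list alone. The ER stress list had 6 higher and 4 lower of 32 (median 0.29, camera adjusted p = 0.0498), and 9 higher and 5 lower adjusted over the list alone. The last 4 lists lost their calls with an estimated correlation (adjusted p = 0.637 for each). With no background subtraction the medians were -0.125 for the epithelial, -0.169 for the matrix, -0.176 for the cytokine and -0.0838 for the Wnt list. With the scanner software's log ratios, whose median over all genes was -0.267, they were -0.684, -0.808, -0.535 and -0.735, or -0.418, -0.541, -0.268 and -0.469 relative to all genes. The ER stress median was 0.375 with those ratios, or 0.642 relative to all genes. Scaled between arrays, the cytokine median was -0.541. Of 57 cell cycle genes, 5 were lower and 1 higher (median -0.26, camera adjusted p = 0.138), and 3 were lower adjusted over the list alone.

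In total 833 probes were higher and 1683 lower in shSnail. The scanner software's log ratios gave 423 and 1927. Without shSnail replicate 1 or replicate 2 the total was 47 or 39, and without shLoxl2 replicate 1 or replicate 2 it was 4278 or 3920. The shLoxl2 arrays were scanned on 1 day with 1 extraction protocol and the shSnail arrays on another day with another, so batch and group cannot be told apart in this comparison.

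Across probes, which are not independent replicates, the log2 fold changes of the 2 silencings had a Pearson correlation of 0.33 and a Spearman correlation of 0.24. Both responses share the shGFP RNA. Simulated unchanged groups sharing 1 control that varied like a silenced sample gave a mean correlation of 0.67, and a covariance of 0.043 beside the observed 0.0868. That simulated correlation follows from its setting, 1 control and n = 2 per group with equal spread, whatever the data. It is therefore no yardstick for the observed 0.33. In both silencings 381 probes rose, where independent lists would share 138.5, and 658 fell, where they would share 144.2. Another 132 rose in shLoxl2 and fell in shSnail, and 52 did the opposite, where independent lists would give 198.1 and 100.8. Those numbers take no account of the shared control. The Pearson correlation was 0.316 with no dye correction of shSnail and 0.349 with the dye effect scaled. With shLoxl2 taken from its Cy3 arrays alone and shSnail as measured, a pairing in which the dye effect enters the responses with opposite signs, it was -0.04.

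**Figure D4:**
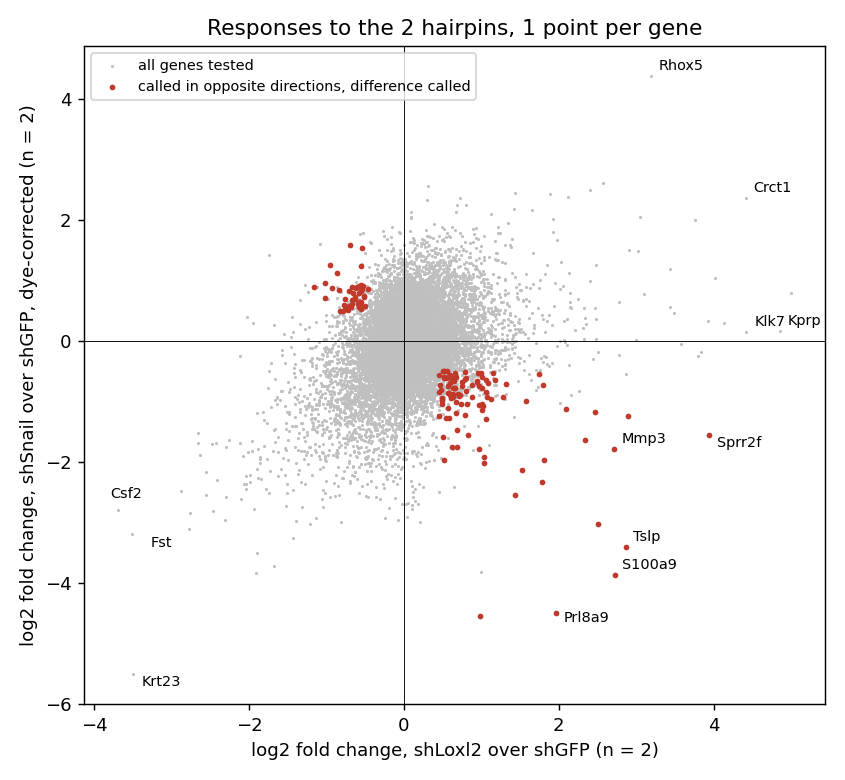
Log2 fold change in shSnail (dye-corrected, vertical axis) against shLoxl2 (horizontal axis) for each gene tested, both over shGFP. Red points were called in opposite directions in the 2 silencings with the difference called. Krt23 lies at -3.49 and -5.51, and S100a9 at 2.72 and -3.87.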

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

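Of the tests here, the one on hairpin effects was chosen only after the result was seen. S100a8 and S100a9, which encode partner calcium-binding proteins, the cytokine Tslp and the prolactin-family gene Prl8a9 differed between the responses to the 2 silencings. These results are listed because shLoxl2 and shSnail, each against shGFP, differed by a test of the difference itself. S100a9 was at 2.72 in shLoxl2 and -3.87 in shSnail, a difference of -6.59. The difference was -6.45 for Prl8a9, -6.25 for Tslp and -5.53 for S100a8. In all, 156 probes were called in opposite directions with the difference called, of which 106 rose in shLoxl2 and 50 fell. The keratinocyte differentiation list had a median difference of -1.05. Each of these differences compares arrays of different scan days, so batch and group cannot be told apart. Each also takes the dye effect as equal on the arrays compared, whereas its slope on the shSnail arrays was 0.449 among dimmer probes. The dye effect on S100a9, Prl8a9, Tslp and S100a8 was small, from 0.0577 to 0.0863.

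Keratinocyte differentiation genes were higher in shLoxl2, with a median of 0.50. The dye as the whole cause is argued against by the medians in both orientations, 0.715 (95% bootstrap interval 0.149 to 0.965) with the silenced RNA in Cy3 and 0.474 (0.164 to 1.01) in Cy5. These intervals resampled the list's genes, which are not independent replicates, and leave out the spread between samples. Cross-hybridisation within gene families stays open. The 31 members outside the Krt, Sprr, Lce, Klk, S100 and Serpinb families had a median of 0.0732. It lay at percentile 87.64 of 10000 random lists matched on expression. The shift of the list's median thus rested on those families and may in part be 1 signal read by several probes. A rise of the separate genes of those families would leave the same median outside them, so this test cannot tell the 2 apart. Of the 31, 9 rose, among them Cnfn by 3.49, and 5 fell. A hairpin effect other than loss of Loxl2 cannot be told apart from that loss, since Loxl2 itself was at 0.111 on a dim probe and no other hairpin was analysed here. Loss of Loxl2 in these cells stays open as an untested biological explanation.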

How the results depend on the processing

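The scaled dye effect, and the scanner software's log ratio on the arrays of the deposited value table, were chosen only after the results were seen. Over 248 named gene and comparison pairs and 3442 alternative values, 2656 kept their direction and side of the threshold, 760 kept their direction without passing (482 of these in settings with 1 array fewer) and 26 reversed. Causes were not tested except where given.

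For shLoxl2 against shGFP, 2728 probes passed. The number was 774 with the scanner software's log ratio, 737 with a 2-fold minimum, 7624 with the Cy5 arrays only and 6705 with the Cy3 arrays only, in which the dye effect does not cancel, and 1733 to 2788 with a replicate left out (1733 without shLoxl2 replicate 1). For shSnail against shGFP, 4203 passed, 1641 with a 2-fold minimum and 1584 to 3144 with a replicate left out (1584 and 1993 without shSnail replicate 1 and 2). For shSnail against shLoxl2, 2516 passed, 1498 with a 2-fold minimum, 4728 at an adjusted p under 0.10, 2709 with the replicate number as a block, and 39 to 4278 with a replicate left out. Where a group had 1 sample, that sample was assumed to vary like the others. The low counts of 47 and 39 came without shSnail replicate 1 and 2. Counts under the other alternatives were within 1.5 times these.

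With the deposited value table limma called 0 probes in each comparison. At an unadjusted p under 0.05 there were 3472 for shLoxl2 against shGFP, 5606 for shSnail against shGFP and 3854 for shSnail against shLoxl2. The scanner software's log ratio on the same arrays also gave 0, with 3468, 5608 and 3864 in the same order, so the loss came with that ratio on fewer arrays and not with the table. With an estimated correlation 0 of 3 gene lists passed in shLoxl2 and 0 of 6 in shSnail. With no background subtraction the medians of called lists lay nearer 0, at 0.231 for keratinocyte differentiation and -0.454 for cell cycle in shLoxl2, and at -0.436 for cell cycle and -0.192 for keratinocyte differentiation in shSnail. With the scanner software's log ratio, whose median over all genes was -0.266 in shSnail, they lay farther from 0 there, at -1.46 for cell cycle, -0.778 for keratinocyte differentiation and -0.953 for growth factor genes (-1.19, -0.512 and -0.687 relative to all genes). Relative to all genes, the EMT and cytokine medians in shSnail lay nearer 0 with that ratio, at -0.515 and -0.357 beside -0.599 and -0.377 in the main fit. The keratinocyte median in shSnail was -0.477 with no dye correction.

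The correlation of the responses, 0.33, was 0.316 with no dye correction and 0.349 with the dye effect scaled. It was -0.041 with Cy3 shLoxl2 arrays and shSnail as measured, where the dye effect enters with opposite signs by construction, 0.20 with the scanner software's log ratio and 0.22 to 0.37 with a replicate left out (0.22 without shLoxl2 replicate 1).

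Among the silenced genes: Loxl2, shLoxl2 against shGFP, at 0.11, was -0.0064 with no background subtraction, -0.99 with the Cy5 arrays only, 1.21 with the Cy3 arrays only and 0.04 to 0.18 with a replicate left out. Snai1 in shSnail had a fitted value of -0.09, and of -0.29 to 0.12 with a replicate left out, which is no measured fold since neither channel was well above background. Snai1 in shLoxl2 ran from -0.33 to 0.093 in the same way, the latter without shLoxl2 replicate 1. Nsdhl in shLoxl2 was -0.38 with the Cy5 arrays only. Loxl2 in shSnail, at 0.27, was -0.11 with no background subtraction, -0.026 scaled between arrays, -0.83 with no dye correction, -0.33 with the dye effect scaled, -0.13 with the deposited table and -0.13 with the scanner software's log ratio on its arrays. With no dye correction of shSnail, Nog was 0.47, Wnt3a 0.063, Cd8a 0.18, Tnnc1 -0.25 and Myh3 0.22, each the reverse of its corrected direction.

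Between shSnail and shLoxl2, Loxl2, at 0.16, was -0.10 with no background subtraction, -0.36 with the scanner software's log ratio, -0.12 scaled between arrays, -0.15 without shLoxl2 replicate 1, and -0.61 with the deposited table and -0.61 with the log ratio on its arrays. Snai1, at 0.03, was -0.073 with no background subtraction, -0.013 without shLoxl2 replicate 1, -0.18 to 0.24 over the replicates left out (-0.18 without shSnail replicate 2), -0.0017 with the deposited table and -0.0034 with the log ratio on its arrays. Nog, at -0.99, was 0.26 with the deposited table and 0.26 with the log ratio on its arrays. Low signal over background limits the Loxl2 and Snai1 values.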

Other observations

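The tests of the dye effect and of its correction on the respiratory chain and ribosome lists, of scan day and of the shared control were chosen only after the results were seen, as were the 3 lists themselves. Genes of the mitochondrial respiratory chain, which carries out oxidative phosphorylation, rose in shSnail cells. The respiratory chain list was picked by symbol from Nduf, Cox, Uqc and Atp5 genes, so it holds ATP synthase genes and leaves out Sdh genes. Adjusted p-values here are over the 3 lists alone. Of 77 genes tested in it, 48 rose and 1 fell, with a median of 0.86 (camera adjusted p = 4.83e-20, and adjusted p = 0.0837 with an estimated correlation). Of 75 mitochondrial ribosome genes, 39 rose and 2 fell, with a median of 0.65 (camera adjusted p = 5.53e-12, and adjusted p = 0.0837 with an estimated correlation). Of 75 cytosolic ribosome genes, 21 rose and 1 fell with dye correction (adjusted p = 0.0424 with an estimated correlation), and 16 rose and 18 fell without it. In shLoxl2 cells the 3 medians were 0.03, 0.07 and 0.15, and none of the 3 lists passed camera.

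The dye effect measured on the shLoxl2 arrays, as the whole cause of the mitochondrial rises, is argued against by the medians with that effect removed, 0.859 (95% bootstrap interval 0.695 to 1.01) for the respiratory chain and 0.645 (0.363 to 0.743) for the mitochondrial ribosome. The intervals resampled genes, which are not independent replicates, and leave out the spread between samples. The correction itself as the cause is argued against by the medians without it, 0.90 and 0.584. A general shift of genes of short genomic span is argued against as well. The highest median among 10000 random lists matched on expression and span was 0.46 for the respiratory chain and 0.35 for the mitochondrial ribosome. These lists were not matched on transcript length, so a shift of short transcripts was not tested and stays open. The cytosolic ribosome median was 0.47 with dye correction, 0.166 with the dye effect scaled and 0.0565 without correction, so the dye correction itself is a candidate source of that rise. Scan day and extraction protocol cannot be told apart from the silencing, since both shSnail arrays were scanned on the other day, and the respiratory chain median against shLoxl2 was 0.84. Loss of Snail stays open as an untested biological explanation.

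Cell cycle genes fell in both silencings. The dye as the whole cause is argued against in shLoxl2 by the medians of -0.711 with the silenced RNA in Cy3 and -0.683 in Cy5. A high level of these genes in the shared shGFP RNA may give both falls, and it cannot be told apart from 2 separate falls because there was 1 control. The median difference between shSnail and shLoxl2 was -0.264. Relative to all genes it was -0.225, and -0.169 with no background subtraction, -0.347 scaled between arrays and -0.00483 with the scanner software's log ratios. Loss of Loxl2 and of Snail stays open as an untested biological explanation.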
